A study of Mus musculus with 12 samples.

How the data were processed

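RNA-seq was done on lung samples of mice whose strain is given in the labels as IRC, with total RNA as the library input per the labels' protocols. The tissue field of the labels reads "Cells", while the titles, the protocol and the series title name lung, and the samples were treated as lung. The titles use BA0 for a group that the series' design text describes under the name B0, and both were taken as the animals given busulfan once. Groups and replicate numbers came from the sample titles, 3 libraries in each of 4 groups.

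The authors deposited 1 table of 19726 genes for the whole series. It holds estimated counts per gene and library, as deposited by the authors without normalisation, of which 75.9 to 77.1% per library were whole numbers. It also holds FPKM values made by the authors, a unit inferred from the values since the deposited headers name none: count divided by library total and by 1 fixed length per gene gave the deposited value, with a median coefficient of variation of the implied length of 0.616%, and the columns sum to between 514938 and 640457. The authors' group means of both units were not used. The genome build was mm10 per the submitters' processing notes, and the aligner, the counting program and their versions are not given in the sources used here. Whether counting used strand is not given either, so reads from overlapping or antisense genes cannot be told apart, and reads of near-identical copies, such as those of the haemoglobin and heat shock families, may be split between them. Of the gene identifiers, 1014 were the sequencing provider's own and the others Entrez gene IDs. Coordinates were taken from the RefSeq annotation of GRCm38, the assembly that mm10 names, by Entrez ID for 15170 of the 15863 genes tested.

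The estimated counts were rounded to whole numbers. Genes were filtered with filterByExpr, library sizes scaled by TMM (factors 0.963 to 1.03), and a negative binomial model with 1 mean per group was fitted to all 12 libraries, which share the estimate of the spread (common biological coefficient of variation 0.229). Contrasts were tested with edgeR 4.0.16's quasi-likelihood F test in R 4.3.3 and Benjamini-Hochberg adjustment, with calls at an adjusted p under 0.05. Alternatives were DESeq2 1.42.0, limma-voom with limma 3.58.1, upper-quartile and median-of-ratios factors, no low-count filter, a minimum of 1 CPM, fits with only the groups compared, the replicate number as a block, a log2 fold change of at least 1, and leaving out each library in turn. The fits with 1 library left out keep at least 2 per group. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9, using numpy 2.4.6 and pandas 2.3.3.

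Before the data were examined, 62 gene lists of pathways, cell types, other tissues and technical signs were fixed, of which 57 had at least 5 measured members. They were tested with limma's camera at a preset correlation of 0.01, with BH adjustment over the lists of a comparison, and again with an estimated correlation and with fry. With the estimated correlation 1 list held for busulfan against control (p53 targets), 3 for each of both against control, both against AOS and the busulfan average (p53 targets, unfolded protein response, senescence), and 0 for the comparisons of AOS and the interaction. Members were counted with adjustment over all genes and over the list alone. The planned comparisons, the test, the alternatives except the median-of-ratios factors, and the rule for naming genes were fixed at the same time. That rule took, per comparison, up to 10 genes in each direction with the smallest p among those past the threshold with an absolute log2 fold change of at least 1, leaving out predicted genes, the 5 smallest p per direction where fewer passed, the 2 to 4 members with the smallest p of each list called by camera, and a set of anchor genes. Some genes that this rule takes are not reported here. Outside this rule, Ccng1, Pmaip1, Ddb2, Cirbp, Fancb and Blm in the busulfan average were chosen after their values were seen, and so was the printing of Zmat3 and Hspa5 levels in the comparisons of AOS. The averages over AOS and over busulfan, and a covariate for conducting airway transcripts, were added after the data had been seen.

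Totals ranged from 16209221 to 17168764 counts. A count of 3, the floor that 0 counts allow, equals 0.175 to 0.185 CPM and covers counting error only. The SE of a gene's log2 fold change was derived as its absolute value divided by the square root of the test's F statistic. The median SE of a log2 fold change was 0.132 for 2 groups of 3. Scgb1a1, the club cell secretory protein gene, took 1.59 to 5.68% of counts, and the haemoglobin genes 0.485 to 2.14%. Principal components of log2 CPM held 21.0, 14.7 and 14.0% of the variance. The 12 pairs of libraries within groups differed by more than sampling noise (chi-square per degree of freedom 18.2 to 40.4), and 0 pairs were identical. The labels do not say whether the 3 libraries of a group came from separate animals, so p-values measure the spread between these samples, which may be technical. No batch, date or lane is given in the labels, so none was modelled.

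The procedure was tested on simulated counts for the comparison of busulfan with control (15730 genes). Each gene was drawn at its mean over all 12 libraries, and changes were planted in the busulfan group only. The procedure recovered 18 of 67 1.5-fold, 35 of 66 2-fold and 55 of 65 4-fold changes, with 4 false calls among 112. Camera at its preset correlation called 5 of 5 shifted and 0 of 45 unshifted lists. Genes were drawn independently and lists at random, so this does not show how often that setting calls lists falsely when genes vary together. Simulated reversal values came from 20 draws in which the combined group had the busulfan means. Agreement of calls was set against the overlap of independent lists.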

Results

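RNA sequencing measured gene expression in the lungs of mice given busulfan, alginate oligosaccharides (AOS), both or neither. Busulfan is an alkylating drug that crosslinks DNA and is used to clear the bone marrow before transplantation. AOS are short sugar chains cut from alginate, a polysaccharide of brown seaweed. The 12 libraries formed 4 groups of 3. Control animals received no treatment, and the AOS group received 10 mg/kg for 5 weeks. The busulfan group received 40 mg/kg once, and the combined group received busulfan once and then AOS at 10 mg/kg for 5 weeks. Library totals ranged from 16209221 to 17168764 estimated counts, and 15863 genes were tested. Levels are given as CPM, normalised by TMM, with the SD over 3 libraries. Changes are given as log2 fold changes with an SE derived from the test's F statistic. Adjusted p-values come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment unless another test is named.

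The comparison of busulfan with control lungs asked what a single dose of the drug changed. Transcripts activated by p53, the transcription factor that responds to DNA damage, were the leading group. Of the 30 measured targets 12 rose and 0 fell, and 16 rose and 1 fell when adjusted over the list alone. Zmat3 (Entrez gene 22401, mm10 chromosome 3, 32334792 to 32365665), which encodes an RNA-binding protein, rose from 18.6 ± 1.23 CPM in controls to 52.7 ± 1.00 CPM after busulfan (SD, n = 3 each), a 2.83-fold rise (SE 0.07 on the log2 scale, edgeR adjusted p = 8.09e-06). Eda2r (Entrez gene 245527, chromosome X, 97333837 to 97377234), a receptor of the tumour necrosis factor receptor family, rose from 3.48 ± 0.324 to 32.8 ± 1.83 CPM. Gdf15 (Entrez gene 23886, chromosome 8, 70629393 to 70632470), a secreted stress cytokine, rose from 1.60 ± 0.564 to 23.1 ± 6.62 CPM. Psrc1, which encodes a spindle-associated protein, rose by 3.06 (SE 0.25), and Phlda3, a repressor of Akt signalling, by 1.43 (SE 0.12) on the log2 scale. The nuclease gene Aen rose by 1.02 (SE 0.09) and the pro-apoptotic gene Bax by 0.92 (SE 0.07). Cdkn1a, the p53-induced inhibitor of cyclin-dependent kinases, stood at 19.9 ± 6.30 CPM in controls and 121 ± 50.7 CPM after busulfan but missed the threshold (edgeR adjusted p = 0.0899). As a list, p53 targets were higher by camera (adjusted p = 1.15e-33, and adjusted p = 0.00176 with an estimated correlation). Leaving out busulfan replicate 2 left 7 of these members past the threshold. The calls of Zmat3, Eda2r, Gdf15, Psrc1, Phlda3, Aen and Bax held in each of the 12 fits that left out a library.

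Genes of the unfolded protein response, which handles misfolded protein in the endoplasmic reticulum, also rose after busulfan: 10 of 16 measured members rose and 0 fell, and 13 rose adjusted over the list alone. Hspa5, the main chaperone of the endoplasmic reticulum, rose from 534 ± 34.8 to 982 ± 158 CPM (SD, n = 3 each), and Manf, a secreted protein of the same compartment, rose by 0.97 (SE 0.10, edgeR adjusted p = 0.00168) on the log2 scale. The co-chaperone gene Dnajb9 rose by 0.63 (SE 0.09) and the calcium-binding chaperone gene Calr by 0.52 (SE 0.07), with adjusted p = 0.0718 for the list with an estimated correlation. The list's count fell to 5 without control replicate 1, 2 without control replicate 2, 4 without control replicate 3 and 5 without busulfan replicate 3. Leaving out control replicate 2 ended the calls of Dnajb9 (edgeR adjusted p = 0.0512) and Calr (0.0621). Of the 14 heat shock and chaperone genes of the cytosol, 0 passed over all genes and 4 adjusted over the list alone (adjusted p = 0.477 with an estimated correlation).

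B cell transcripts were lower after busulfan. Of 19 measured B cell markers, 6 fell and 0 rose, 18 fell adjusted over the list alone, and the median log2 fold change was -1.42 (camera adjusted p = 1.63e-24, adjusted p = 0.163 with an estimated correlation). Pax5, the transcription factor that maintains B cell identity, fell by 1.73 on the log2 scale (SE 0.32), and Cd79a, a signalling chain of the B cell receptor, fell from 43.3 ± 14.8 to 15.3 ± 2.91 CPM (SD, n = 3 each). Outside that list, H2-Ob, which encodes a regulator of antigen presentation made in B cells, fell by 1.87 on the log2 scale (SE 0.26), the receptor gene Gpr18 by 1.46 (SE 0.21) and the B cell receptor-like gene Fcrl1 by 1.67 (SE 0.25). Of 21 T cell markers 1 fell (3 adjusted over the list alone), the chemokine receptor gene Ccr7 (-1.58, SE 0.31), with adjusted p = 0.526 for the list with an estimated correlation. Markers of other tissues and of airway cells had negative medians too, with 0 members past the threshold over all genes by edgeR. The median log2 fold change was -7.88 for 19 skeletal muscle genes (15 lower adjusted over the list alone, adjusted p = 0.526 with an estimated correlation), -3.91 for 16 liver genes (14 lower adjusted over the list alone, adjusted p = 0.526 with an estimated correlation), -1.42 for 14 club and goblet cell genes and -0.54 for 38 ciliated cell genes (0 members adjusted over the list alone, adjusted p = 0.546 and adjusted p = 0.587 with an estimated correlation). The muscle and liver medians rest on uneven control libraries. The skeletal muscle score was -0.15, 7.39 and 3.71 in control replicates 1, 2 and 3, and -0.87 to 0.15 after busulfan. For liver it was 2.18, 2.50 and 5.56 in controls and 0.16 to 1.69 after busulfan. Adjustment over the list alone thus also called genes of tissues that were high in single control libraries. The calls among B cell genes were fragile, with 0 of the 19 markers called by limma-voom and 15 by DESeq2. The number of B cell markers that fell became 0 without control replicate 2 or 3, AOS replicate 1 or 2, busulfan replicate 2 or 3, or busulfan + AOS replicate 2. It became 1 without AOS replicate 3 and 3 without busulfan replicate 1 or busulfan + AOS replicate 3. Pax5 and Ccr7 lost their calls without control replicate 2 or 3, AOS replicate 1 or 2, any busulfan replicate, or busulfan + AOS replicate 2 (edgeR adjusted p up to 0.129 and 0.148). Cd79a lost its call without these and without AOS replicate 3 (up to 0.167). H2-Ob and Gpr18 lost theirs only without control replicate 2 (edgeR adjusted p = 0.0556 and 0.0584), and Fcrl1 without control replicate 2 or 3 or busulfan replicate 2 or 3 (up to 0.0694).

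Over all genes, 192 of 15863 passed in the comparison of busulfan with control, 116 higher and 76 lower (83 and 95 with upper-quartile scaling), and DESeq2 called 975. With edgeR the count was 82 without control replicate 1, 35 without control replicate 2, 51 without control replicate 3, and 99 and 92 without AOS replicates 1 and 2. It was 112, 75 and 52 without busulfan replicates 1, 2 and 3, and 90 without busulfan + AOS replicate 2. It was 13 when only these 6 libraries entered the fit.

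**Figure D1:**
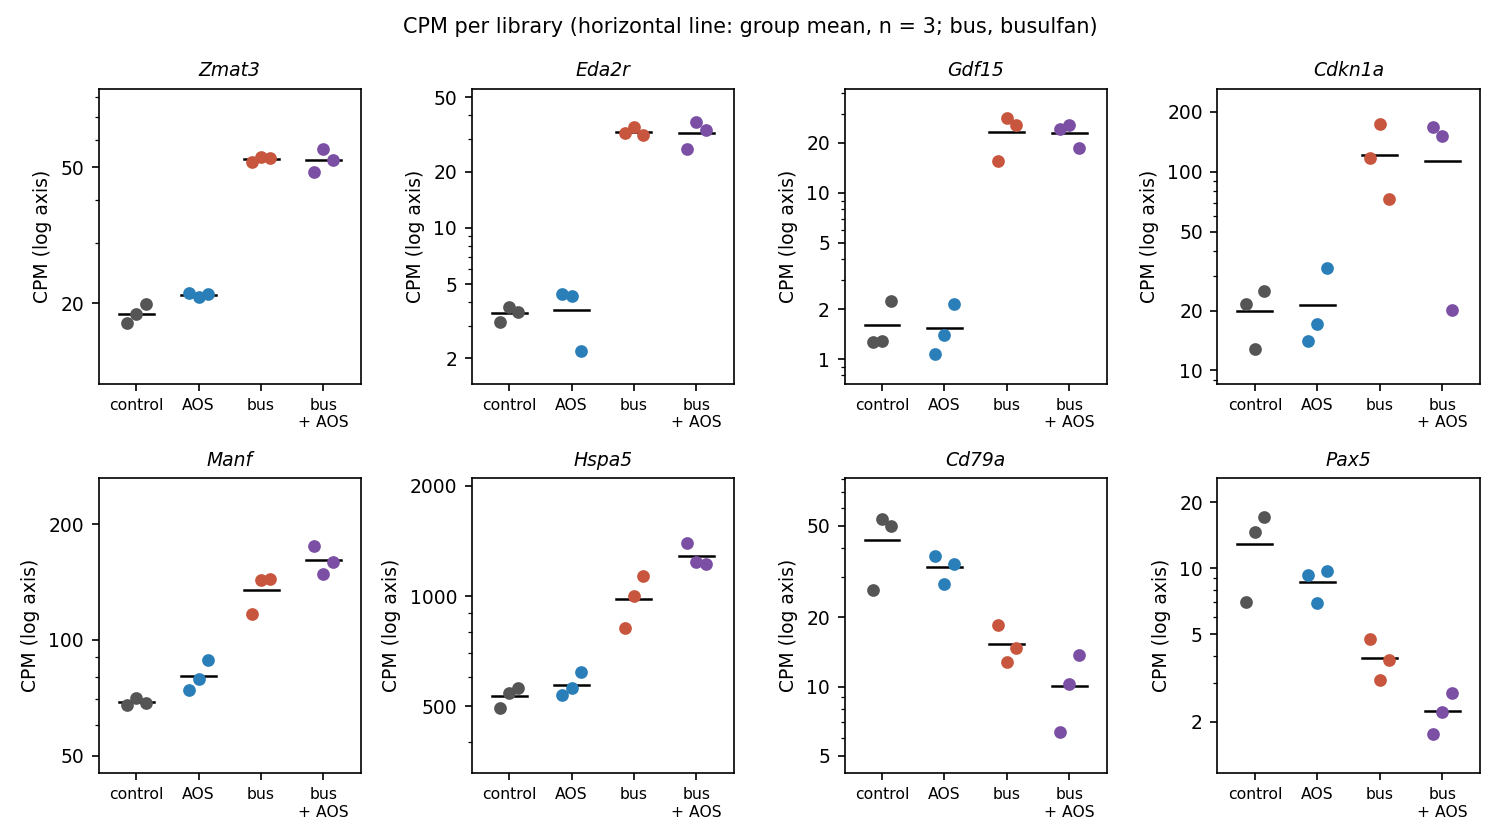
CPM of selected genes in each of the 12 libraries, grouped by treatment on the x axis, with a log scale on the y axis; each point is a library and each line marks the mean of 3. Zmat3 lies near 18.6 CPM in controls and near 52.7 CPM after busulfan, while the B cell gene Cd79a lies near 43.3 and 15.3 CPM.

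The combined group was compared with the AOS group to ask what busulfan changed in animals that also received AOS. No library is shared with the comparison of busulfan with control. The p53 targets again led: 12 of 30 rose and 0 fell (18 rose and 2 fell adjusted over the list alone, camera adjusted p = 3.62e-30, adjusted p = 0.00233 with an estimated correlation). Zmat3 rose by 1.31 (SE 0.07, edgeR adjusted p = 3.09e-05), Eda2r by 3.15 (SE 0.23), Gdf15 by 3.89 (SE 0.33) and Sesn2, a stress-induced regulator of growth signalling, by 1.13 (SE 0.14) on the log2 scale. Ephx1, a detoxifying epoxide hydrolase, rose from 172 ± 9.12 to 347 ± 13.2 CPM (SD, n = 3 each). Of the 16 unfolded protein response genes 13 rose and 0 fell (15 adjusted over the list alone, adjusted p = 0.0105 with an estimated correlation), among them Hspa5 by 1.17 (SE 0.11), Calr by 0.70 (SE 0.07) and Hsp90b1, a chaperone of secreted proteins, by 0.75 (SE 0.08). Of 14 heat shock and chaperone genes 10 rose (13 adjusted over the list alone, adjusted p = 0.108 with an estimated correlation), including Hspa8, the constitutive cytosolic chaperone, by 1.33 (SE 0.24) and its co-chaperone Dnaja1 by 1.74 (SE 0.33). B cell markers fell in 8 of 19 cases and rose in 0 (17 fell adjusted over the list alone, adjusted p = 0.108 with an estimated correlation), against 1 by limma-voom and 16 by DESeq2. Pax5 fell by 1.96 (SE 0.33), Fcer2a, the low-affinity receptor for immunoglobulin E, by 2.20 (SE 0.39) and Cd22, an inhibitory receptor, by 1.61 (SE 0.29) on the log2 scale. The lectin gene Cd209d (-2.64, SE 0.41), the nuclear receptor gene Rorb (-2.17, SE 0.30) and the receptor tyrosine kinase gene Kit (-0.88, SE 0.15) fell too. Of 19 erythroid genes 3 fell, including the alpha globin gene Hba-a1 (-1.46, SE 0.30) and the haem synthesis gene Alas2 (-1.30, SE 0.29). Adjusted over the list alone 9 fell and 2 rose (adjusted p = 0.317 with an estimated correlation), and the median of the list (-0.60) and its mean (0.18) differ in sign. Hba-a1 has a near-identical paralog, Hba-a2, so the split of reads between these copies is uncertain. The platelet list was lower too, with a mean log2 CPM of 2.21 ± 0.42 with AOS and 1.34 ± 0.25 with both (SD, n = 3 each). It stood at 1.67 ± 0.29 in controls and 1.64 ± 0.46 after busulfan alone, so this difference was not seen without AOS. Its genes Alox12 (-1.25, SE 0.28) and Nrgn (-1.68, SE 0.38) fell (edgeR adjusted p = 0.0466 and 0.0478). Nrgn stood at 11.4 ± 3.74 CPM in controls, 20.6 ± 8.60 with AOS, 8.95 ± 3.31 after busulfan and 6.43 ± 1.18 with both. The fat list stood at 3.87 ± 1.83 with AOS, highest in replicate 1 (5.82), and at 1.73 ± 0.80 with both.

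In total 365 genes passed between the combined and the AOS group, 247 higher and 118 lower (199 and 198 with upper-quartile scaling), and DESeq2 called 1249. The edgeR count was 220 without control replicate 2, 42, 67 and 132 without AOS replicates 1, 2 and 3, and 87 and 64 without busulfan + AOS replicates 1 and 2. Calls of Zmat3, Eda2r, Gdf15, Sesn2, Ephx1, Hspa5, Calr and Hsp90b1 held in each of the 12 fits that left out a library. Those of Hspa8 and Kit ended without AOS replicate 1 or 2 or busulfan + AOS replicate 1 or 2 (edgeR adjusted p up to 0.0969 and 0.0805). Those of Pax5 and Cd22 ended without AOS replicate 1 or 3 or the same 2 combined replicates (up to 0.0801 and 0.102), and those of Dnaja1 and Fcer2a without any AOS replicate or the same 2 (up to 0.107 and 0.0962). Rorb lost its call without AOS replicate 1 or busulfan + AOS replicate 2 (up to 0.0559), and Cd209d without those or busulfan + AOS replicate 1 (up to 0.0704). Hba-a1 and Alas2 lost theirs without control replicate 3, busulfan replicate 1 or any replicate of the 2 groups compared (up to 0.133 and 0.154). Heat shock members past the threshold numbered 0 without AOS replicate 1 or 2 or busulfan + AOS replicate 1 or 2, 3 without AOS replicate 3, and 5 without control replicate 1 or 2 or busulfan replicate 2. B cell members numbered 0 without AOS replicate 1 or 3 or busulfan + AOS replicate 1 or 2, and 2 without AOS replicate 2.

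Against untreated controls, the combined group showed changes in the same gene groups. The same 3 combined libraries enter this comparison and that with the AOS group, so part of this likeness is built in. Of the p53 targets 14 of 30 rose (18 rose and 2 fell adjusted over the list alone, adjusted p = 0.00181 with an estimated correlation). Of the unfolded protein response genes 13 of 16 rose (15 adjusted over the list alone, adjusted p = 0.0102 with an estimated correlation), and of the heat shock and chaperone genes 10 of 14 (13 adjusted over the list alone, adjusted p = 0.178 with an estimated correlation). B cell markers fell in 15 of 19 cases (17 adjusted over the list alone, adjusted p = 0.0707 with an estimated correlation), against 12 by limma-voom and 17 by DESeq2. Hspa5 stood at 1286 ± 96.6 CPM, a log2 rise of 1.27 (SE 0.11), and Manf rose by 1.23 (SE 0.10). Pax5 fell by 2.54 (SE 0.33) and Cd79a fell by 2.10 (SE 0.31) on the log2 scale. Pmepa1, a gene induced by TGF-beta, rose by 0.68 (SE 0.09), and the ubiquitin ligase gene Rnf144a fell by 1.02 (SE 0.13). These 6 genes kept their calls in each of the 12 fits that left out a library. Il33, an alarmin cytokine gene, rose by 0.64 (SE 0.10, edgeR adjusted p = 0.0110), a call that ended without control replicate 2 (0.0527). Altogether 648 genes passed, 386 higher and 262 lower (295 and 377 with upper-quartile scaling), and DESeq2 called 1414. The edgeR count was 203, 129 and 261 without control replicates 1, 2 and 3, 380 and 385 without AOS replicates 1 and 2, and 179 and 171 without busulfan + AOS replicates 1 and 2. Heat shock members past the threshold numbered 0 without control replicate 1 or 2, 3 without control replicate 3, 4 without AOS replicate 1 or 2, 6 without busulfan replicate 2, and 1 without busulfan + AOS replicate 1 or 2. B cell members numbered 7 and 8 without control replicates 2 and 3, and 7 and 6 without busulfan + AOS replicates 1 and 2.

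The busulfan effect averaged over animals with and without AOS, a comparison added after the data had been seen, set 6 libraries against 6. It gave 1877 genes, 1114 higher and 763 lower (767 and 1092 with upper-quartile scaling). Of the p53 targets 18 of 30 rose and 1 fell (19 rose and 3 fell adjusted over the list alone, adjusted p = 0.00106 with an estimated correlation). Cdkn1a rose by 2.51 (SE 0.48, edgeR adjusted p = 0.0106) and the cyclin gene Ccng1 by 0.79 (SE 0.09) on the log2 scale. The pro-apoptotic genes Bbc3 and Pmaip1 rose by 0.72 (SE 0.13) and 1.25 (SE 0.15), and the DNA damage sensor gene Ddb2 fell by 0.32 (SE 0.08) on the log2 scale. The unfolded protein response list had 14 of 16 members higher (14 adjusted over the list alone, adjusted p = 0.0151 with an estimated correlation) and the heat shock list 12 of 14 (14 adjusted over the list alone, adjusted p = 0.170 with an estimated correlation). Hspb1, a small heat shock protein gene, rose by 1.62 (SE 0.29), Hsp90ab1 by 0.85 (SE 0.14) and Pdia4, a disulfide isomerase gene, by 0.64 (SE 0.06). B cell markers fell in 17 of 19 cases (19 adjusted over the list alone, adjusted p = 0.0874 with an estimated correlation), with Spib lower by a log2 fold change of -1.50 (SE 0.20) and Cd22 at -1.52 (SE 0.20). Of 13 genes for antigen presentation on MHC class II 2 fell (3 adjusted over the list alone, adjusted p = 0.590 with an estimated correlation), H2-Ob (-1.69, SE 0.19) and H2-Oa (-2.05, SE 0.36), which encode the chains of the modulator H2-O.

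Structural, epithelial and other transcripts were examined in this averaged comparison as well. Of 16 alveolar type 1 cell markers, from the flat epithelium of gas exchange, 7 rose and 0 fell (8 adjusted over the list alone, adjusted p = 0.170 with an estimated correlation), among them Cldn18, a tight junction gene, by 0.48 (SE 0.07), the proteoglycan gene Spock2 by 0.37 (SE 0.07) and Ager, the receptor for advanced glycation end products, by 0.24 (SE 0.05). Of 28 extracellular matrix genes 6 rose (7 adjusted over the list alone, adjusted p = 0.590 with an estimated correlation), including Lox, a collagen crosslinking enzyme, by 0.59 (SE 0.10), Postn by 0.41 (SE 0.08) and the proteoglycan gene Bgn by 0.30 (SE 0.06). Among 16 senescence genes 3 rose, Gdf15, Cdkn1a and Igfbp7 (3 adjusted over the list alone, adjusted p = 0.0320 with an estimated correlation), and the first 2 of these also belong to the p53 list. T cell markers fell in 3 of 21 cases (3 adjusted over the list alone, adjusted p = 0.624 with an estimated correlation), namely Cd27 (-0.90, SE 0.15), Ccr7 (-1.27, SE 0.22) and Zap70 (-0.59, SE 0.14). Of 20 genes of xenobiotic metabolism 3 fell and 1 rose (7 and 1 adjusted over the list alone, adjusted p = 0.624 with an estimated correlation), the 3 being the oxidase genes Aox3 (-0.65, SE 0.10) and Fmo1 (-0.36, SE 0.07) and the esterase gene Ces1f (-0.69, SE 0.14). Besides these lists, the transcription factor gene Creb5 rose by 1.42 (SE 0.15), and the progesterone receptor gene Pgr fell by 1.08 (SE 0.14). Anchor genes of the main lung compartments, namely Sftpc, Scgb1a1, Foxj1, Col1a1, Mki67, S100a8, Cd3e and Tmprss2, did not pass. The median log2 fold changes of 14 club and goblet cell genes (-0.84), 38 ciliated cell genes (-0.33), 19 skeletal muscle genes (-3.57) and 16 liver genes (-1.59) were negative as well, and none of these lists held with an estimated correlation. In them 1 club and goblet cell gene (0 adjusted over the list alone, adjusted p = 0.654 with an estimated correlation) and 2 skeletal muscle genes (2 adjusted over the list alone, adjusted p = 0.624 with an estimated correlation) fell. The muscle and liver scores differed widely between libraries of one group here too. The count of 1877 became 1234 and 1079 without control replicates 1 and 2, 1153 and 1155 without AOS replicates 1 and 2, 1148 without busulfan replicate 3 and 1103 without busulfan + AOS replicate 2. Zap70 lost its call without control replicate 2 or busulfan replicate 3 (edgeR adjusted p up to 0.0528).

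**Figure D2:**
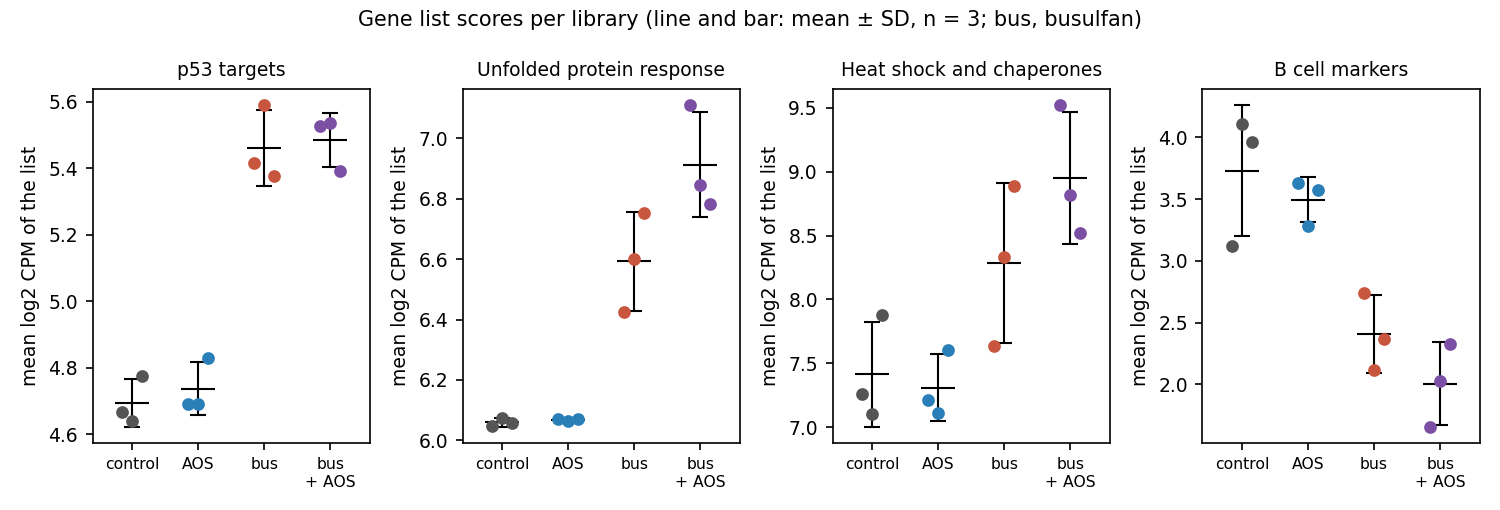
Mean log2 CPM of the members of gene lists in each of the 12 libraries, by group on the x axis; points are libraries and bars mark the mean of 3 with its SD. All 6 busulfan libraries lie above the other 6 for p53 targets and the unfolded protein response and below them for B cells, and 5 of 6 lie above for heat shock and chaperones.

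The list scores, taken as the mean log2 CPM of a list's members in each library, separated the animals given busulfan from the others. For p53 targets, the unfolded protein response, senescence and alveolar type 1 cells all 6 busulfan libraries lay above the other 6, and for B cells all 6 lay below (two-sided exact permutation test over 924 relabelings, p = 0.00216 each, the smallest these allow, adjusted p = 0.0247 over the 57 lists). The unfolded protein response score was 6.06 ± 0.01 without busulfan and 6.75 ± 0.23 with it (SD, n = 6 each). For heat shock and chaperones and for fibroblasts 5 of 6 lay above, and for thymus markers 5 of 6 lay below (adjusted p = 0.0308 for fibroblasts and for thymus). Tests of 3 libraries against 3 by exact permutation cannot give a p below 0.10 and were not used.

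The effects of busulfan measured without AOS and with AOS share no library, so their agreement has no part that comes from shared controls. Across the 15863 genes, which are not independent replicates, the log2 fold changes correlated with Spearman's rho 0.462 and Pearson's r 0.105, and 69.9% of genes had the same sign. Of the 192 genes called without AOS, 187 (97.4%) changed in the same direction with AOS. Called in both were 73 higher genes, against 1.81 for independent lists, and 34 lower genes, against 0.565, and 0 were called in opposite directions. Both comparisons come from 1 fit and share each gene's estimate of the spread. Genes with a small estimate are favoured in both, so the overlap of independent lists is too low a reference.

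**Figure D3:**
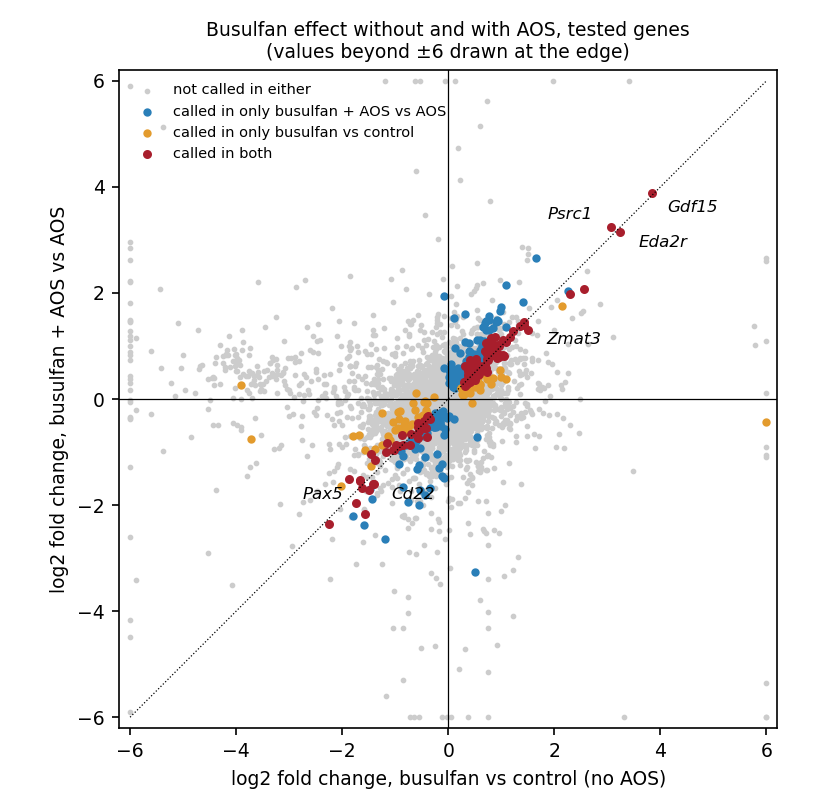
Log2 fold change of each tested gene after busulfan without AOS (x axis, busulfan against control) and with AOS (y axis, busulfan + AOS against AOS); each point is a gene and colours mark genes called in both, in only the first or only the second comparison. Psrc1 lies at 3.06 and 3.24, Eda2r at 3.23 and 3.15, and Pax5 at -1.73 and -1.96.

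The comparison of AOS with control lungs asked what AOS alone changed. No p53 target, chaperone or B cell gene passed, and over all genes edgeR called 0, with 642 (4.05%) at an unadjusted p under 0.05; limma-voom called 0 and DESeq2 called 11. The named genes with the smallest p included Tmem265, at 1.64 ± 0.267 CPM in controls and 3.80 ± 0.494 CPM with AOS (log2 fold change 1.21, SE 0.20, edgeR adjusted p = 0.619), the splicing gene Usp39 (-0.52, SE 0.09), Sh2d4a (-0.41, SE 0.07), Sh3rf2 (-0.42, SE 0.09) and Banp (0.47, SE 0.10). Zmat3 stood at 18.6 ± 1.23 CPM in controls and 21.2 ± 0.289 CPM with AOS, and Hspa5 at 534 ± 34.8 and 573 ± 42.2 CPM (SD, n = 3 each). The cholesterol synthesis list had a median of -0.28 over 18 genes (camera adjusted p = 1.64e-13, adjusted p = 0.533 with an estimated correlation), with Stard4 at -0.38 (SE 0.11). The interferon-stimulated list had a median of 1.28 over 25 genes (2.82e-11, adjusted p = 0.957 with an estimated correlation), and its mean log2 CPM was 3.96, 6.23 and 4.76 in AOS replicates 1, 2 and 3 against 4.09 to 4.26 in controls, so the shift rests mainly on replicate 2. Of both lists 0 members passed over all genes or adjusted over the list alone. The fat list had a median of 2.44 over 16 genes, with 0 members over all genes and 11 adjusted over the list alone (adjusted p = 0.533 with an estimated correlation), and Adipoq, a fat cell hormone gene, reached 122 CPM in AOS replicate 1 against 17.1 CPM or less in the other libraries. Leaving out control replicate 3 gave 1 gene in place of 0. With a median SE of 0.132 on the log2 scale, and with 18 of 67 simulated 1.5-fold and 35 of 66 2-fold changes recovered in the comparison of busulfan with control, small effects were not detectable in most genes at this size.

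The comparison of the combined group with busulfan alone asked whether AOS altered lungs already exposed to busulfan. By edgeR 0 genes passed, with 1006 (6.34%) at an unadjusted p under 0.05; limma-voom called 0 and DESeq2 called 29. The immediate early gene Ier5 had the smallest p, at 68.0 ± 1.89 CPM after busulfan and 97.9 ± 6.27 CPM after both (log2 fold change 0.53, SE 0.07, edgeR adjusted p = 0.414). Small p-values were also found for Aph1b (0.33, SE 0.06), a subunit gene of gamma-secretase, the oxidase gene Aox1 (0.87, SE 0.17), Gpihbp1 (-0.34, SE 0.07), which anchors lipoprotein lipase to capillaries, and Sh3rf2 (-0.43, SE 0.09). The p53 targets had a median log2 fold change of 0.03, with 52.4 ± 3.98 CPM of Zmat3 after both and 52.7 ± 1.00 CPM after busulfan. Of the 16 unfolded protein response genes 0 passed over all genes and 7 adjusted over the list alone (median 0.26, camera adjusted p = 5.98e-13, adjusted p = 0.417 with an estimated correlation), and Hspa5 stood at 982 ± 158 CPM after busulfan and 1286 ± 96.6 CPM after both. B cell markers had a median of -0.41, with 0 members past either threshold (adjusted p = 0.464 with an estimated correlation). Ciliated cell genes had a median of 0.47 (0 members adjusted over the list alone, adjusted p = 0.464 with an estimated correlation) and liver genes one of 3.28 (12 members adjusted over the list alone, adjusted p = 0.417 with an estimated correlation). The liver score was uneven within the combined group, at 5.10, 3.06 and 1.38 in replicates 1, 2 and 3.

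Whether AOS moved the genes changed by busulfan back towards control was asked of the 192 genes called for busulfan. In the comparison of both with busulfan alone 100 of them (52.1%) had the opposite sign and 0 were called in the opposite direction, and the median share of the busulfan log2 fold change left in the combined group was 99.4%. Both comparisons share the 3 busulfan libraries, which by itself yields opposite signs: in 20 simulations where the combined group was drawn at the busulfan means, 68.8% of the genes had the opposite sign (58.9 to 74.0%) and the median share left was 88.9% (84.7 to 94.9%). The observed share of opposite signs lay below its range. It was 35.3% without control replicate 3 and 63.0% with DESeq2, each computed on the genes called there, for which no range was simulated. Each draw took the 192 genes with the smallest p and drew genes independently, so the simulated ranges may be too narrow for genes that vary together. Across the 15863 genes the log2 fold changes of these comparisons had Pearson's r -0.687 and a covariance of -0.304, both more negative than simulated (-0.313 to -0.206 and -0.0992 to -0.0610). Spearman's rho was -0.241, less negative than simulated (-0.280 to -0.254), so the measures point different ways. These values lay outside their simulated ranges, so the draws are no sure reference for the share of opposite signs or the share left. Whether AOS moved the genes back towards control cannot be told from these draws.

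The interaction asked whether the effect of AOS differed between animals with and without busulfan. By edgeR 0 genes passed, with 760 (4.79%) at an unadjusted p under 0.05; limma-voom called 0 and DESeq2 called 16, and leaving out control replicate 3 gave 1 gene by edgeR. The heat shock list was higher by camera (median 0.75, adjusted p = 8.85e-08, adjusted p = 0.556 with an estimated correlation) with 0 of 14 members past either threshold. The effects of AOS with and without busulfan correlated across genes with Spearman's rho 0.0474 and Pearson's r -0.190. Averaged over busulfan, a comparison added after the data had been seen, AOS gave 0 genes by edgeR, 847 (5.34%) at an unadjusted p under 0.05, 0 by limma-voom and 13 by DESeq2, and 1 by edgeR without control replicate 3. There Sh2d4a (-0.35, SE 0.05, edgeR adjusted p = 0.351) and Sh3rf2 (-0.42, SE 0.06, edgeR adjusted p = 0.351) had the smallest p, and 6 of 12 genes for antigen presentation on MHC class I passed adjusted over the list alone (adjusted p = 0.474 with an estimated correlation), with H2-D1 at 0.43 (SE 0.10). The list's mean log2 CPM was 5.46 in AOS replicate 2 and 5.12 and 5.81 in busulfan + AOS replicates 2 and 3, against 4.05 to 4.99 in the other libraries, and interferon-stimulated genes were high in those 3 as well.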

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

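The count of other splits behind each number of called genes, and the tests of hypoxia, glucocorticoid response, lymphoid tissue, blood and airway, were chosen after the results were seen; those of the clock genes and of Rbm3 were written before their own values were seen, though Cirbp had been seen by then.

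For 10 of the 129 genes and lists screened, an effect pointed in opposite directions in the 2 arms, with the 3 libraries of each group fully apart in both. For 9 of them this was the effect of AOS with and without busulfan, and for Xk that of busulfan with and without AOS. The differences were not shown by a test, since the interaction gave an adjusted p of 0.989 for each by edgeR, and most of these genes had been named for their small interaction p, so opposite signs are common among them by selection. The difference of the AOS effect with busulfan less that without, in log2 CPM, was -0.53 for Iah1 (0.41 without and -0.12 with busulfan), 0.43 for Aph1b, 1.08 for Aox1, 0.85 for Xk, -1.23 for Plcxd3, 0.31 for Mecom, 3.14 for Scrg1, -3.92 for Csprs and -0.34 for Slc50a1. For Gp1bb it was -6.17, a value set by the prior count, since all 3 control and all 3 combined libraries held 0 counts and the other 6 held 0.24 to 1.85 CPM.

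The number of genes called was set against other splits of the same libraries. For the busulfan average 1 of 40 splits, the real one, called as many as 1877 genes, and the highest of the others called 4. A count of that size was thus rare among splits of these libraries, but a share of 1 in 40 does not exclude chance. The comparison itself was added after the data had been seen. For busulfan against control (192 genes, highest other split 2), both against control (648, highest other 0) and both against AOS (365, highest other 1), 1 of 10 splits reached the real count, and 10 splits are too few for a share under 0.05. Where edgeR called 0 genes in the real split, any split calls at least as many, so the count of splits says nothing about chance. This holds for AOS against control and both against busulfan (10 of 10 splits, highest other 1 and 0) and for the interaction and the AOS average (40 of 40 splits, highest other 0 and 1).

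The rise of chaperone and unfolded protein response genes after busulfan was weighed against the handling of animals and tissue. Another time of day is argued against by the clock genes, whose evening genes less morning genes differed by 0.168 log2 CPM (SE 0.0937), and hypoxia before lysis by the hypoxia list, which differed by 0.0443 (SE 0.0531). Warmer tissue or animals stays open, since the cold-induced genes Rbm3 (-0.32, SE 0.06) and Cirbp (-0.79, SE 0.08) were both lower after busulfan, as that explanation needs. Stress of the animals with glucocorticoid release stays open too, since the glucocorticoid response list without Cdkn1a, a p53 target, was higher by 0.449 (SE 0.133). A response to busulfan itself also stays open and was not tested apart from these.

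The fall of B cell transcripts after busulfan was weighed against the makeup of the tissue pieces. A piece with less lymphoid tissue of every kind in equal measure is argued against by the T cell list, since B cell genes fell further by -1.11 log2 CPM (SE 0.139), though the T cell (-0.299, SE 0.137) and natural killer cell scores (-0.615, SE 0.281) and thymus markers (-0.43) were lower too. For busulfan against control, less blood is argued against by the haemoglobin share of counts, since the B cell list fell further than its log2 by -1.15 (SE 0.371). For both against AOS less blood stays open, since the share was 0.485 to 0.765% against 1.39 to 1.94% and the difference was -0.0528 (SE 0.371). A loss of B cells and unequal numbers of B cell follicles in the pieces were not tested and stay open.

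Ciliated and club and goblet cell scores spread widely within groups. With group means removed they correlated over the 12 libraries (Pearson's r 0.768, permutation p = 0.00416, and Spearman's rho 0.741, permutation p = 0.00786). Without the 2 libraries farthest from the median r was 0.718. The permutations took the 12 values as free although group means had been removed, so these p-values are likely too small. Pieces with different amounts of conducting airway would give such a correlation, but this stays open. In control replicates 1, 2 and 3 the club and goblet score was 7.19, 6.12 and 4.76. Scgb1a1 varied less there, at 4.11, 4.03 and 3.61% of counts. The acute phase and epithelial defence list stood at 6.76, 5.81 and 4.39. No biological explanation was tested for a spread within groups.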

How the results depend on the processing

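The averaged comparisons, the airway covariate, the median-of-ratios factors and the member counts with a library left out were chosen after the results were seen. The other alternatives were fixed before. Of the counts, list counts and agreement values 298 stayed within their limits and 89 moved. Of the single genes, lists and member counts 20347 kept direction and side of the threshold or, for member counts, stayed within their limits. Among genes and lists 963 lost the call, 252 gained one and 7 turned direction, and 53 member counts moved. Values called in neither setting were taken as kept, and their sign changes were not counted. The 20347 therefore do not measure how stable the calls were. The cause of a move was not tested, except that fits with fewer libraries have fewer degrees of freedom. Depth limits genes near 0.175 CPM, where a library holds 3 counts. The pseudocount alternative was not run, since counts were at hand.

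Genes called by DESeq2 numbered 975 (492 higher, 483 lower) for busulfan against control, 1414 for both against control, 1249 for both against AOS, 11 for AOS against control, 29 for both against busulfan, 16 for the interaction and 13 for the AOS average. With only the groups compared in the fit the first 3 counts were 13, 166 and 191, and with a log2 fold change of at least 1 they were 47, 134 and 81, and 177 for the busulfan average. The airway covariate gave 87 for busulfan against control, with 1 B cell marker in place of 6, 6 unfolded protein response genes in place of 10 and 8 p53 targets in place of 12. Upper-quartile factors gave 178 there, 83 higher and 95 lower, against 116 higher and 76 lower with TMM. For both against control these factors gave 295 higher and 377 lower, for both against AOS 199 and 198, and for the busulfan average 767 and 1092, so the share of higher calls depends on the scaling.

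With 1 library left out, the counts ranged from 35 to 230 for busulfan against control, 129 to 710 for both against control, 42 to 492 for both against AOS, 1079 to 1667 for the busulfan average, and 0 to 1 for AOS against control, the interaction and the AOS average (1 without control replicate 3). 

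The replicate numbers did not pair the libraries: 2 of 18 same-numbered pairs of libraries correlated above 0.1, the mean was -0.0589 against 0.0294 for other pairs, and 2 of 12 libraries correlated best with their own number. With the number as a block the counts were 55, 281 and 163 for busulfan against control, both against control and both against AOS. B cell markers called with the block numbered 0, 8 and 3 there, against 6, 15 and 8 without it. Heat shock genes called with the block went from 10 to 4 for both against control and from 10 to 2 for both against AOS, and for busulfan against control p53 targets went from 12 to 7 and unfolded protein response genes from 10 to 7. With the block 43.6% of the genes called for busulfan had the opposite sign with AOS.

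Lists called by camera numbered 26, 12, 29, 22, 19, 25, 29 and 23 for busulfan against control, AOS against control, both against busulfan, both against control, both against AOS, the interaction, the busulfan average and the AOS average. An estimated correlation gave 1, 0, 0, 3, 3, 0, 3 and 0, and fry 6, 0, 0, 5, 9, 0, 11 and 0. With a library left out camera called 12 to 22 lists for AOS against control and 19 to 29 for both against AOS.

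The correlation of busulfan effects was 0.312 without a low-count filter, 0.521 with the stricter one and 0.354 to 0.495 with a library left out, where that of AOS effects was -0.0718 to 0.111. The share of opposite signs was 63.0% with DESeq2 and 35.3 to 56.5% with a library left out.

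Lists called by camera turned direction in 7 cases, all past their threshold before and not after; direction is that of camera's statistic, and in 2 of the cases the median kept its sign (skeletal muscle for AOS against control, interferon-stimulated genes). With a library left out the medians ranged from -2.16 to 0.44 for cardiac muscle and -4.87 to -0.28 for skeletal muscle (AOS against control), -5.89 to 0.52 for skeletal muscle (both against control), 0.0147 to 1.31 for interferon-stimulated genes (both against busulfan) and -0.00363 to 0.63 for immediate early genes (interaction). The turns came without AOS replicate 1, control replicate 2, control replicate 2, busulfan + AOS replicate 3 and control replicate 3. With the airway covariate the club and goblet list, part of that covariate, gave -0.000996 for both against busulfan and -0.0722 for the AOS average.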

Other observations

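Interferon-stimulated genes differed between libraries more than between groups. Their mean log2 CPM was 6.23 in AOS replicate 2, 5.58 in busulfan replicate 2, 5.52 and 6.67 in busulfan + AOS replicates 2 and 3, and 3.96 to 4.76 in the other 8 libraries. Ifit1, an antiviral gene, stood at 118, 65.0, 71.1 and 172 CPM in those 4 and at 25.8 CPM or less in the others. Repair genes for crosslinks, the lesion that busulfan makes, moved little: 2 of 22 fell in the busulfan average and 0 rose (3 fell and 1 rose adjusted over the list alone, adjusted p = 0.840 with an estimated correlation, with a median of -0.02 and a mean of 0.02 that differ in sign), namely Fancb (-0.68, SE 0.10) and Blm (-0.61, SE 0.16), both chosen after their values were seen. Plasma cell genes did not fall with the B cell genes, with 1 of 9 higher in the busulfan average and 0 lower (1 adjusted over the list alone, adjusted p = 0.624 with an estimated correlation).

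Transcripts of neighbouring tissues were high in single libraries. Albumin (Alb) stood at 683 CPM in control replicate 3 and 482 CPM in busulfan + AOS replicate 1, against 6.28 CPM in busulfan replicate 1. The skeletal muscle list had a mean log2 CPM of 7.39 in control replicate 2 and 4.58 in busulfan + AOS replicate 3. It stood at 3.76 in AOS replicate 1 and 3.71 in control replicate 3. The myosin gene Myh4 ran otherwise, at 42.8 CPM in control replicate 2 and 77.0 CPM in AOS replicate 1. The fat gene Adipoq stood at 122 CPM in AOS replicate 1. Medians of the liver, muscle and fat lists rest on such libraries.

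The beta globin genes Hbb-bs and Hbb-bt, which belong to another haplotype than Hbb-b1, stood at 819 and 140 CPM in busulfan + AOS replicate 3 and at 15.5 and 3.88 CPM or less elsewhere. Hbb-b1 stood at 1094 CPM in that library, the lowest of the 12, and at up to 7458 CPM in control replicate 2. Reads may be shared between these copies, a limit that also bears on the call of Hbb-bs for both against control (log2 fold change 10.14), which ended without any control or AOS replicate and without busulfan replicate 1 or 2 (edgeR adjusted p up to 0.124). Cdkn1a stood at 20.3 CPM in busulfan + AOS replicate 3, against 168 and 152 CPM in replicates 1 and 2 and 12.9 to 32.8 CPM in the 6 libraries without busulfan, while the p53 list score of that library, 5.39, lay within the range of the other busulfan libraries, 5.38 to 5.59.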
